A study of Mus musculus with 8 samples.

How the data were processed

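Splenic Tregs of C57BL/6 mice, sorted as GFP-positive cells, were profiled by RNA sequencing from SMART-Seq v4 libraries (a kit that amplifies full-length cDNA from small amounts of RNA). There were 8 libraries in 4 groups of 2: SRC-3KO and control, each from mice without a tumor and from tumor-bearing mice. The labels put both no-tumor controls in the same group, but replicate 1 is named as wild type and its source label does not mention GFP, while replicate 2 and both tumor controls are named as Foxp3-Cre. The names of both SRC-3KO no-tumor libraries, and of no other library, carry the word Tam1, whose meaning is not given in the sources used here. If it stands for a treatment, that treatment cannot be separated from genotype without a tumor. Per the labels, the authors used the mouse genome build mm10 and the tools FastQC, Trim Galore, STAR, featureCounts and edgeR, with no versions, and file and column names add StringTie. The strand setting and the annotation release are not given in the sources used here.

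The deposited counts table holds raw read counts of 55487 genes for the 4 no-tumor libraries. The deposited FPKM table holds StringTie FPKM values of the same number of genes for the 4 tumor libraries. No library is in both. Gene positions, GC content and transcript lengths came from GENCODE vM21, to which 55141 genes matched by ID. GC content and length are those of the longest transcript and were known for 99.94% and 99.89% of the genes tested. Totals were 27452922 and 31075452 counts in the SRC-3KO and 25251597 and 24159217 in the control no-tumor libraries. The depth of the tumor libraries is unknown, and their FPKM sums were 514349 and 463082 (control) and 416186 and 408458 (SRC-3KO). Mitochondrial genes were listed at 0 in both tables.

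The groups, the comparisons, the gene lists and the rule for naming genes were fixed before the data were examined. That plan was 1 edgeR fit of all 8 libraries, which the split into tables of different units ruled out. Without a tumor, edgeR 4.0.16 (R 4.3.3) was used on counts with filterByExpr, TMM factors (0.916 to 1.086) and the quasi-likelihood test (common dispersion 0.791). With a tumor, limma 3.58.1 with an intensity trend was used on log2(FPKM + 1), for genes with at least 1 FPKM in at least 2 libraries (total degrees of freedom 5.37). The states were combined by summing signed z values with equal weight (Stouffer) over the 11674 genes tested in both. The difference between states was the difference of the voom and limma log2 fold changes, read against the t distribution with the smaller of the 2 degrees of freedom. Satterthwaite degrees of freedom were the first choice and were replaced after their result and a simulated test were seen. Of the 5 planned gene comparisons, tumor against no tumor was not tested. p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05.

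Of 28 fixed lists of genes, those with at least 3 tested members, 22 in each state, were tested with camera (preset correlation 0.01) on voom values or log2(FPKM + 1), and again with an estimated correlation and with fry. fry tests whether a list moves, on balance, in a direction, and does not compare it with other genes. Members were also adjusted over the list alone. List medians without a tumor are of voom log2 fold changes. Values of single genes there, and counts of members below 0, are from edgeR. Named genes were, by rule, up to 10 each way among genes with an adjusted p under 0.05, groups that do not overlap and a mean of at least 10 in the table's unit, without predicted, ribosomal and antigen receptor segment genes, plus Ncoa3, Foxp3, the sex-linked list and up to 4 members per list with the smallest adjusted p. Some list members that this rule names are not reported here, in the text or the plots. In the text, rose, fell and called refer to a passed test.

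The pipeline was tested on simulated data built from these tables. For counts with a dispersion of 0.1, it recovered 29.7% of genes changed by 1.5 and 97.2% of genes changed by 3.0 (log2), with 6 false of 139 calls. At the dispersion estimated here it recovered 0, with 0 calls. For FPKM with a moderated spread it recovered 79.5% and 98.0%, with 22 false of 188 calls, and with the unmoderated spread of these data, shuffled over genes, 22.9% and 68.0%, with 1 false of 88 calls. The moderated version was added after the other was seen. The difference between states was simulated only with counts at a dispersion of 0.1, not at the 0.791 estimated here. In it the smaller degrees of freedom gave 0 false of 168 calls and Satterthwaite 19 false of 209, while the shuffled spread recovered 0. A simulated fall by 1 of the cell cycle list in the tumor table was called, with 0 other lists.

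Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters, a pseudocount of 0.1, a replicate block, omission of antigen receptor segment, haemoglobin and ribosomal protein genes, and leaving out each library. Chosen after seeing the data were scaling of FPKM by median-of-ratios or quantiles, removal of a loess trend (span 0.5) with GC content and length per library, omission of the first control no-tumor and the second control tumor library together, and the Satterthwaite version.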

Results

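Regulatory T cells (Tregs) are CD4 T cells that express the transcription factor Foxp3 and restrain other immune cells. SRC-3, encoded by Ncoa3, is a coactivator that nuclear receptors recruit to switch on genes. Splenic Tregs labelled SRC-3KO were compared with control Tregs by RNA sequencing, with 2 libraries per group, in mice with and without a tumor. The question was how the transcriptome of Tregs that lack SRC-3 differs from that of control Tregs. The labels do not say that the replicates came from separate animals, so the p-values measure only the spread between samples, which may be technical. The no-tumor libraries were read as counts, the tumor libraries as FPKM, fragment counts scaled to transcript length and library size. Each change is a log2 ratio of SRC-3KO over control with its standard error (SE) from 2 libraries per group.

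Ncoa3 (ENSMUSG00000027678, mm10 chromosome 2, 165992636 to 166073242, plus strand) was lower in both SRC-3KO no-tumor libraries, at 39.6 and 26.7 CPM (counts scaled to library size), than in the controls, at 132 and 54.1 CPM. The log2 fold change was -1.48 (SE 0.83) and did not pass edgeR's quasi-likelihood test (adjusted p = 0.910). It was -0.80 without control replicate 1 (adjusted p = 0.282), and it passed as lower without control replicate 2 (adjusted p = 0.0114). In the tumor libraries Ncoa3 stood at 41.6 ± 5.41 FPKM in control and 37.6 ± 14.0 FPKM in SRC-3KO (SD, n = 2). SRC-3KO replicate 1, at 47.5 FPKM, lay above both controls. That change was -0.18 (SE 0.30, limma adjusted p = 0.770), and -0.67 with the GC and length trend removed (limma adjusted p = 0.383). Both states combined gave -0.83 (adjusted p = 0.991). The deleted exons are not given in the sources used here, so transcripts of the rest of the gene may be counted and these values do not test the labels.

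Foxp3 (chromosome X, 7573644 to 7595245, plus strand), which defines the Treg lineage, stood at 21.1 and 10.2 CPM in SRC-3KO and 231 and 20.5 CPM in control without a tumor. Its change was -3.01 (SE 1.30, edgeR adjusted p = 0.910) and rested on control replicate 1. It was -0.48 without that library and -3.89 without control replicate 2, where that library is the only control. With the GC and length trend removed it was -1.34 (edgeR adjusted p = 0.985). With a tumor it stood at 24.4 ± 6.16 FPKM in SRC-3KO and 16.6 ± 2.61 FPKM in control (SD, n = 2), a change of 0.52 (SE 0.25, limma adjusted p = 0.363). The change was 0.77 without SRC-3KO replicate 1, 0.27 without SRC-3KO replicate 2 and 0.24 with the GC and length trend removed. The related coactivators Ncoa1 and Ncoa2 changed by less than their tests could call, at -1.11 and -0.22 without a tumor and 0.48 and 0.49 with one.

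**Figure D1:**
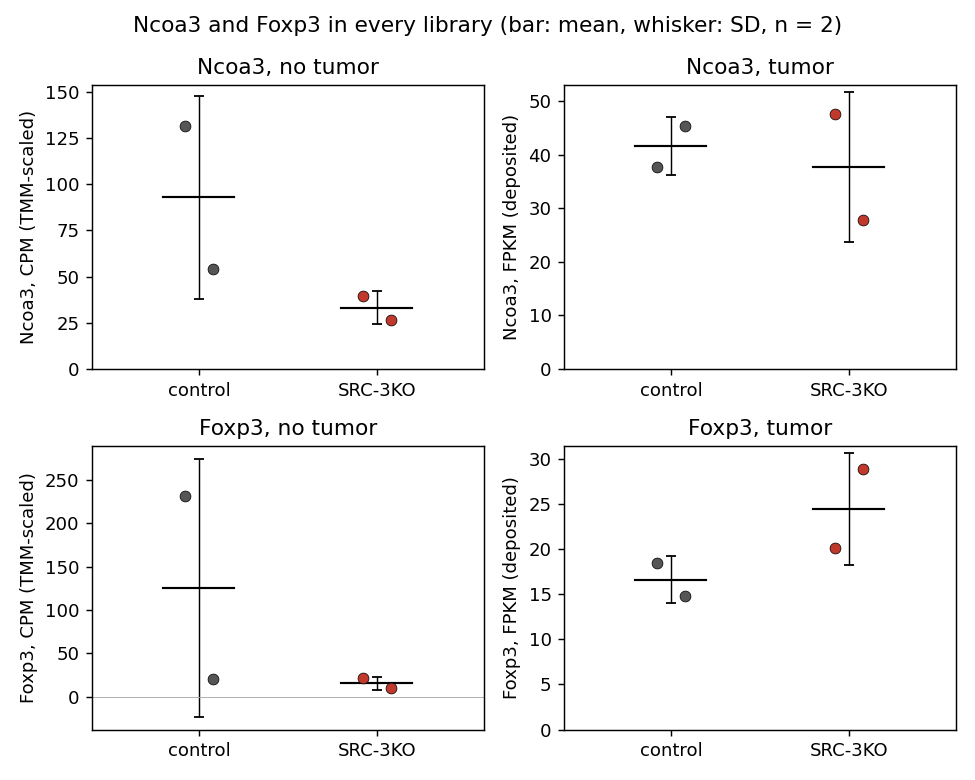
Ncoa3 and Foxp3 in each library, in CPM for the no-tumor libraries and FPKM for the tumor libraries. Points are libraries, bars are means and whiskers are SD (n = 2); control no-tumor replicate 1 is the highest for both genes, at 132 and 231 CPM.

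In tumor-bearing mice, the SRC-3KO libraries had lower levels of plasma cell and B cell transcripts and of Apoe. Summed over the B cell list, the controls held 2202 and 6308 FPKM and the SRC-3KO libraries 473 and 483 FPKM. The share of B lineage cells among the sorted cells was not measured, so these changes may not be of Tregs. Apoe, a lipid carrier (chromosome 7, 19696109 to 19699188, minus strand), fell from 41.4 ± 2.27 to 1.43 ± 0.0578 FPKM (SD, n = 2), a log2 fold change of -4.12 (SE 0.20, limma adjusted p = 0.0117). It stood at 39.8 and 43.0 FPKM in the controls. In control replicate 1 the macrophage genes Lyz2 and Csf1r stood at 0.404 and 0 FPKM. In control replicate 2 they stood at 1108 and 57.7 FPKM, so Apoe did not follow them. Jchain, the joining chain of secreted antibodies (chromosome 5, 88519809 to 88527891, minus strand), fell by 5.39 (SE 0.32, adjusted p = 0.0204). Ly6d, a surface protein of early B lineage cells (chromosome 15, 74762056 to 74763620, minus strand), fell from 25.2 to 0.822 FPKM (adjusted p = 0.0460). The antibody light chain Igkc fell by 5.34 (SE 0.39) and the B cell receptor component Cd79a by 2.96 (SE 0.24). Snora73b, a small nucleolar RNA (chromosome 4, 132352322 to 132352526, minus strand), rose from 0.237 to 24.4 FPKM (adjusted p = 0.0163). Its locus overlaps Rcc1, whose own levels overlapped between the groups (38.2 and 27.6 FPKM in control, 29.3 FPKM in SRC-3KO replicate 2). The microRNA gene Mir24-2 (chromosome 8, 84208815 to 84208921, plus strand) was listed at 0 in both controls and at 880 and 904 FPKM in SRC-3KO (adjusted p = 0.000145). It lies within the lincRNA Gm26532 on the same strand, listed at 0 and 0.126 FPKM in control and 2.55 and 2.62 FPKM in SRC-3KO, so its value may hold reads of that transcript.

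These were among 14 of 12859 genes called by limma, 2 up and 12 down, with 2119 genes at an unadjusted p under 0.05. Mzb1 (-3.91) and Ifitm1 (-3.96), a plasma cell chaperone and an interferon-induced membrane protein, also fell and were chosen after their values were seen, as were the antibody gene segments Igkj1, Ighj2, Ighj4, Ighv6-3 and Ighv11-2, which completed the 14. Scaling the FPKM by median-of-ratios called 2 up and 4 down. Without control replicate 1 the call covered 459 genes and without control replicate 2 it covered 2510, and in each of these fits 8 of the 14 passed the filter on low values and all 8 were called. Of the genes called, 207 were called in the same direction in both.

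Treg identity genes rose with a tumor, 6 of 20 members when adjusted over the list alone and 0 over all genes. The transcription factors Ikzf4 and Ikzf2 rose by 1.24 (SE 0.18) and 1.37 (SE 0.28). Itgae, the integrin chain CD103, rose by 1.36 (SE 0.20). The inhibitory receptor Ctla4 rose from 144 ± 10.4 to 260 ± 40.4 FPKM, and Il2ra, the alpha chain of the IL-2 receptor, from 291 ± 0.361 to 559 ± 87.8 FPKM (SD, n = 2). The inhibitory receptor Tigit rose by 0.86 (SE 0.23). The list median was 0.63 (limma camera adjusted p = 1.44e-05, and 0.386 with an estimated correlation). B cell transcripts were higher in both controls (list median -2.17) and myeloid transcripts in control replicate 2, and the share of such cells was not measured. Effector Treg genes went both ways, 7 up and 2 down of 23 over the list alone (median 0.38, camera adjusted p = 0.020, and 0.348 with an estimated correlation). The growth factor Areg rose by 1.84 (SE 0.22), the IL-33 receptor Il1rl1 by 2.34 (SE 0.47) and the transcription factor Rora by 1.01 (SE 0.19), while the calcium-binding S100a4 and S100a6 fell by 1.62 and 1.81. Klrg1, Lag3 (1.02), Batf (0.96) and Prdm1 (0.88) also rose. Without control replicate 1 the effector list was not called, at a median of 0.31 (adjusted p = 0.231).

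TGF-beta signalling genes rose, 9 of 14 over the list alone and 0 over all genes (median 0.70, camera adjusted p = 9.93e-07, and 0.354 with an estimated correlation). With the trend with GC content and transcript length removed, the median was 0.41 and 4 of 14 rose over the list alone. The B cell list fell in the same libraries (median -2.17). The inhibitor Smad7 rose by 1.52 (SE 0.23), and the integrin chains Itgb8 and Itgav, which activate latent TGF-beta, by 1.49 (SE 0.24) and 1.39 (SE 0.21). Tgfb1 rose from 46.8 and 59.7 FPKM to 104 and 100.2 FPKM. Smad3 (0.73), Ski (0.67), Tgfbr2 (0.58), Tgfbr3 (0.84) and Smad4 (0.53) also rose.

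Genes of resting or central T cells fell, 5 of 17 over the list alone (median -0.39, camera adjusted p = 0.00159, and 0.348 with an estimated correlation). The median was -0.24 without control replicate 1 and -0.68 without control replicate 2. The B cell list fell in the same libraries (median -2.17), and B cells also express Ccr7 and Bach2. The chemokine receptor Ccr7 fell by 0.86 (SE 0.21), the surface protein Ly6c1 by 1.78 (SE 0.25), the transcription factor Bach2 by 1.45 (SE 0.27) and the kinase Txk by 1.30 (SE 0.25). Homing receptors as a list had a median of 0.17 (adjusted p = 0.798), with 3 members up and 3 down over the list alone. Among these the gut homing receptor Gpr15 rose by 1.66 (SE 0.23) and the integrin chain Itgal by 0.80, while Ccr2 fell by 1.04.

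Cell cycle genes fell, 14 of 34 over the list alone and 0 over all genes (median -0.80, camera adjusted p = 1.31e-12, and 0.348 with an estimated correlation and 0.0548 by fry). The B cell list fell in the same libraries (median -2.17). The mitotic kinases Aurkb and Plk1 fell by 1.72 (SE 0.24) and 1.39. Ube2c, which marks mitotic proteins for decay, fell from 6.74 and 7.24 to 1.66 and 1.61 FPKM. Birc5, which acts in mitosis, fell by 1.44, and Rrm2, which makes deoxynucleotides, by 1.35 (SE 0.21). Stmn1 (-1.66), Ccna2 (-1.04), E2f1 (-0.89), Cdca8, Nusap1, Bub1, Kif11, Ccnb2 and Ccne1 were the rest. The list kept its median of -0.80 without control replicate 2 (adjusted p = 4.47e-07).

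Effector cytokines fell, 6 of 14 over the list alone with 1 up (median -1.55, camera adjusted p = 0.000481, and 0.348 with an estimated correlation). In the same libraries the B cell list fell (-2.17), and the monocyte (-3.34) and neutrophil (-5.60) lists were high in control replicate 2. The chemokines Ccl3 and Ccl4 fell by 2.78 (SE 0.34) and 2.59 (SE 0.37), and Csf2, Il17a, Il17f and the perforin gene Prf1 by 1.91, 2.44, 2.57 and 1.40. Il5 rose from 0.303 and 0 to 2.19 and 3.46 FPKM. The median was -0.54 without control replicate 1 (adjusted p = 0.0191), and without control replicate 2 the list was not called (-0.63, adjusted p = 0.106). The immediate early list rose as a set (median 0.28, adjusted p = 0.0115, and 0.348 with an estimated correlation), with Cd83 up by 1.18 (SE 0.19) over the list alone, and was not called without SRC-3KO replicate 1, at a median of 0.26 (adjusted p = 0.0577). The IL-2 and STAT5 list had a median of 0.25 (adjusted p = 0.268).

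Interferon-induced genes were lower as sets, with 0 members called over their lists alone or over all genes. The type I list had a median of -1.24 (camera adjusted p = 0.000549) and the gamma list -0.48 (adjusted p = 0.00159), and both had an adjusted p of 0.570 with an estimated correlation. Zbp1, a sensor of nucleic acids, stood at 48.1 and 137 FPKM in control and 24.4 and 21.3 in SRC-3KO, and Irf8 at 177 and 210 against 98.2 and 108. Control replicate 2 decided both calls. Without it the medians were 0.07 (adjusted p = 0.750) and -0.25 (adjusted p = 0.517).

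Oxidative phosphorylation and ribosomal protein genes fell as sets, with medians of -0.50 (camera adjusted p = 4.8e-12, 77 genes) and -0.36 (adjusted p = 2.73e-06, 85 genes) and 0 members called over either list alone or over all genes. With an estimated correlation the adjusted p was 0.509 and 0.611. In the same libraries the B cell list fell (median -2.17), and myeloid transcripts were high in control replicate 2. With the trend with GC content and transcript length removed the medians were -0.30 and -0.17. The oxidative phosphorylation median was -0.23 without control replicate 1 and -0.76 without control replicate 2. Ndufc1, a subunit of respiratory complex I, stood at 64.3 and 46.4 FPKM in control and 30.2 and 30.1 in SRC-3KO, and Rps13 at 72.3 and 45.3 against 34.8 and 33.1. Without control replicate 1 the ribosomal list was not called (median -0.00358, adjusted p = 0.445), and without control replicate 2 its median was -0.72. Nuclear receptors and coregulators rose as a set (median 0.42, adjusted p = 0.000481, and 0.348 with an estimated correlation), with 3 of 20 members up over the list alone, among them the acetyltransferase Ep300 by 1.57 (SE 0.29) and the retinoic acid receptor Rara by 0.76 (SE 0.18). Removing the same trend took that median to 0.06 (adjusted p = 0.154), with 0 members up over the list alone. Cholesterol synthesis genes (median 0.18, adjusted p = 0.0339, and 0.621 with an estimated correlation) lost their call with that trend removed (median 0.09, adjusted p = 0.142). They also lost it without control replicate 2, at a median of -0.06, and without SRC-3KO replicate 2, at 0.15. Glycolysis (0.10, adjusted p = 0.699) and heat shock (-0.17, adjusted p = 0.285) genes were not called.

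B cell transcripts moved with genotype in the tumor libraries, while neutrophil and most monocyte transcripts were high in control replicate 2 alone. The B cell list fell by a median of 2.17 (camera adjusted p = 4.24e-10, and 0.348 with an estimated correlation), with 8 of 11 members called over the list alone and Cd79a and Igkc over all genes. Its median was -5.08 without control replicate 1. The antibody heavy chain Ighm fell from 646 and 657 to 239 and 201 FPKM, and the antigen-presenting H2-Aa, H2-Ab1 and H2-Eb1 by 4.03, 4.38 and 3.75. The monocyte list had a median of -3.34 (adjusted p = 0.000591, 6 genes, and 0.509 with an estimated correlation). Of its members Apoe was called over all genes, and it stood alike in both controls (39.8 and 43.0 FPKM). The neutrophil list had a median of -5.60 (adjusted p = 0.0421, 3 genes, and 0.509 with an estimated correlation). The neutrophil proteins S100a8 and S100a9 stood at 1851 and 1570 FPKM in control replicate 2 and at 1.38 and 1.55 in control replicate 1. Without control replicate 2 the monocyte median was -0.59 (adjusted p = 0.158), and the neutrophil list had a median of -5.32 with the trend removed (adjusted p = 0.0604). The cytotoxic genes Nkg7 and Gzma fell by 1.62 and 1.95 over their list alone, though the CD8 T and NK cell list was not called (adjusted p = 0.216). Igfbp4 of the conventional CD4 T cell list fell by 0.95 (list adjusted p = 0.268), and the dendritic cell gene Zbtb46 had a change of 0.80 (SE 0.26) as the only member tested. With fewer than 3 members tested, the erythroid gene Car2 (0.06, SE 0.27), the stromal genes Pecam1 (-0.62, SE 0.37) and Epcam (0.06, SE 0.30) and the sex-linked Xist (0.61, SE 0.26) were not tested as sets, and no platelet or mitochondrial genes were tested.

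With the tumor, camera called 16 of 22 lists, 6 up and 10 down, but 0 with an estimated correlation between genes (smallest adjusted p = 0.348) and 0 by fry (smallest 0.051). Fold changes rose with transcript length across genes, which are not independent replicates, from a median of -0.40 in 521 genes under 1000 bases to 0.45 in 429 genes over 8000 bases. Members beyond the 4 with the smallest adjusted p of each list were chosen after their values were seen.

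**Figure D2:**
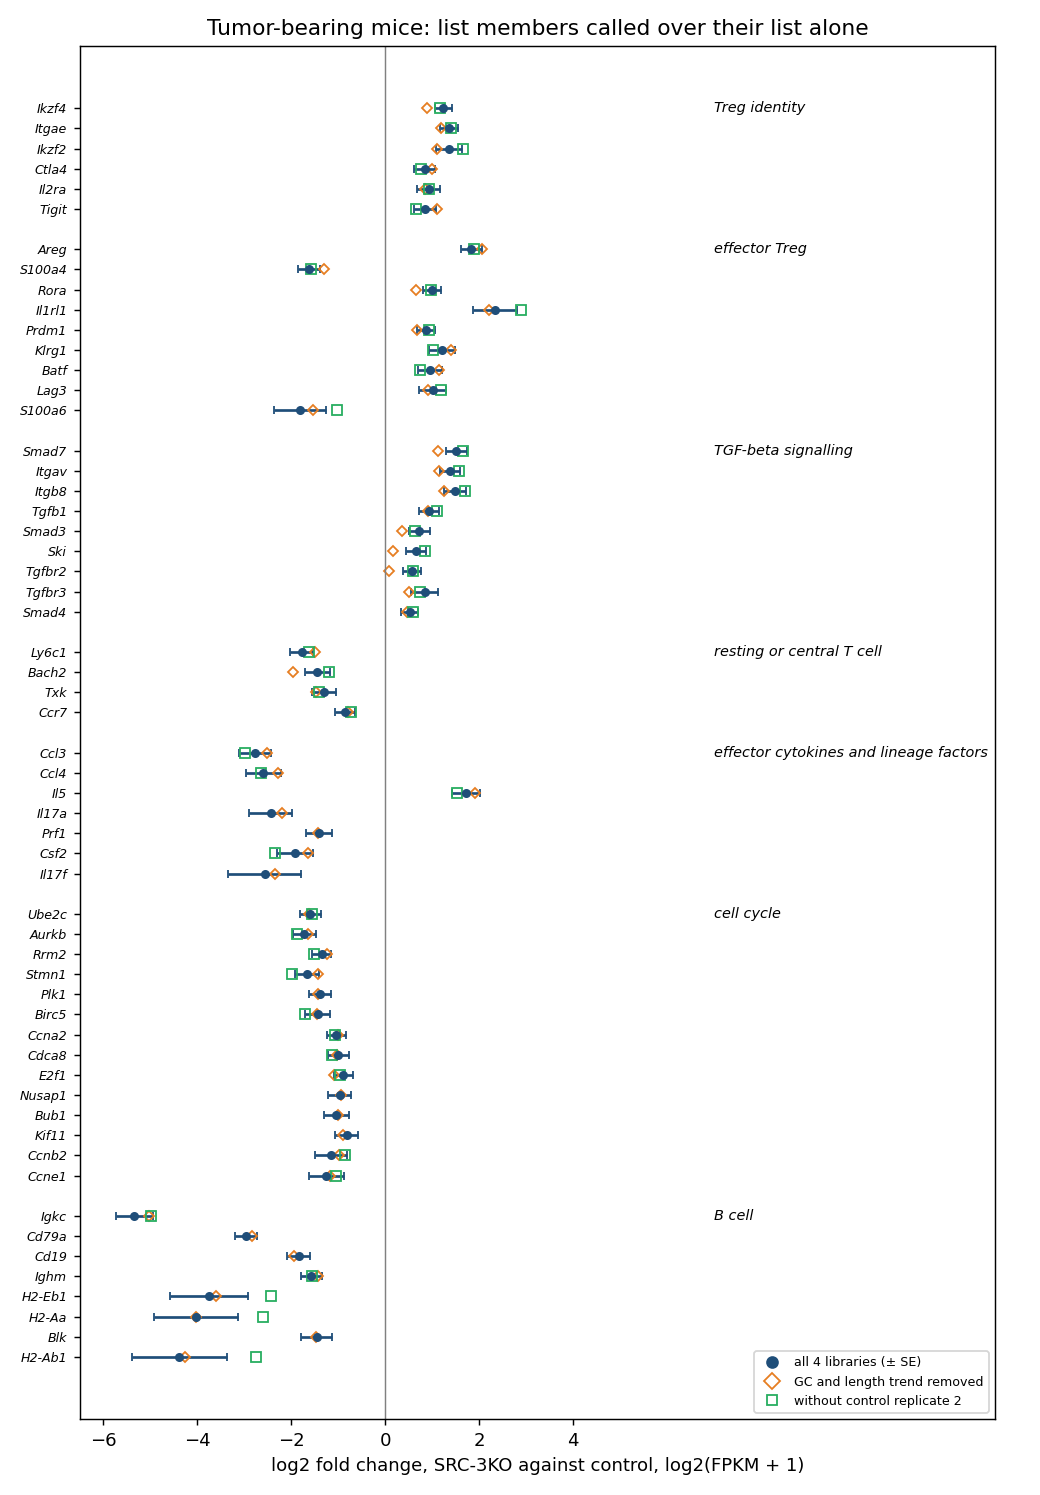
Log2 fold change ± SE (SRC-3KO over control, tumor-bearing mice, n = 2 per group) of members of 7 lists called over their list alone. Circles are all 4 libraries, diamonds the values with the GC and length trend removed, squares the values without control replicate 2 (none where a gene was then not tested); Ikzf4 at 1.24 and Ly6c1 at -1.78 lie on opposite sides.

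Without a tumor, the mitotic kinase gene Aurkb was lower in both SRC-3KO libraries than in both controls, though no single gene passed the test over all genes. It stood at 3.23 and 5.52 CPM in SRC-3KO against 284 and 30.6 CPM in control, a log2 fold change of -5.17 (SE 1.36). Ccna2 (-4.59, SE 1.49), E2f1 (-3.37, SE 1.16) and the proliferation marker Mki67 (-3.32) were lower in both SRC-3KO libraries as well, among 40 cell cycle genes tested. Of the 40, 16 lay lower and 3 higher in both SRC-3KO libraries than in both controls. Without any effect, 33.3% of orderings of 2 against 2 would not overlap. Relative to the control mean, the list median was 0.67 and -0.67 in control replicates 1 and 2. It was -1.46 and -0.73 in SRC-3KO, so replicate 2 lay near control replicate 2. The costimulatory receptor Tnfrsf9 stood at 1015 ± 111 CPM against 285 ± 261 CPM (SD, n = 2), and Ikzf2 at 225 and 209 against 40.9 and 155. Nt5e, which makes adenosine, had a change of 2.11 (SE 0.92). The dendritic cell receptor Xcr1 fell when adjusted over the 3 members tested of its list (0.0484), from 2.03 and 1.49 CPM to 0 in both SRC-3KO libraries. The platelet integrin Itga2b stood at 0.556 and 1.14 CPM in control and 0 in both SRC-3KO libraries, and as the only member tested of its list its p of 0.0313 had no adjustment. No member of any other list passed over its list alone. In total, edgeR's quasi-likelihood test called 0 of 14860 genes (smallest adjusted p = 0.910), with 472 genes at an unadjusted p under 0.05. limma-voom called 0 (380 at an unadjusted p under 0.05) and DESeq2 called 86, 18 up and 68 down.

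Camera called 7 of 22 lists without a tumor. Lower as sets were cell cycle (median -1.09, adjusted p = 4.4e-07, 35 of 40 genes below 0), nuclear receptors and coregulators (-1.35, adjusted p = 0.000229) and conventional CD4 T cell genes (-1.19, adjusted p = 0.0277). Higher were type I interferon response (1.72, adjusted p = 0.00792), interferon gamma response (1.29, adjusted p = 0.0176), oxidative phosphorylation (1.56, adjusted p = 1.3e-06) and ribosomal protein genes (1.06, adjusted p = 0.000705). These rested on control replicate 1, without which their medians were 0.46, 0.16, -0.05 and -0.34. With an estimated correlation 0 lists were called (smallest adjusted p = 0.80), and 0 by fry (smallest 0.524). With the trend with GC content and transcript length removed, the nuclear receptor median was 0.08 (adjusted p = 0.197). The interferon-induced Usp18 stood at 33.2 and 62.8 CPM against 4.25 and 15.7 CPM, Iigp1 at 612 and 559 against 17.6 and 310 CPM, and Tgtp2 at 150 and 126 against 1.87 and 65.5 CPM. Oas1a had a change of 2.47 (SE 1.10), the retinoid receptor Rxra -3.67 (SE 1.27), and the methyltransferase Carm1 -2.50 (SE 0.98). The conventional CD4 T cell gene Pde3b stood at 1.09 and 2.25 CPM against 21.6 and 5.26 CPM.

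The other lists without a tumor were not called. Treg identity had a median of 0.61 (adjusted p = 0.211), effector Treg 0.08 (0.769), resting T cell 0.25 (0.884) and homing 0.36 (0.852). Members included Gata3 (-1.71, SE 0.92), Tcf7 (-1.98, SE 0.96), Satb1 (-1.80, SE 0.83) and Cxcr6 (2.16, SE 0.93). Cytokines had a median of -0.82 (0.330), with Il2 at -3.05 (SE 1.18). Immediate early genes had -0.61 (0.0578), IL-2 and STAT5 response -0.49 (0.154), with Ccnd3 at -3.05, and TGF-beta signalling -0.29 (0.509), with Tgfbr1 at 1.67. Heat shock had 1.16 (0.165), with Hspa8 at 1.42, glycolysis -0.76 (0.128), and cholesterol synthesis -0.09 (0.401), with Lss at -3.15. Among other cell types, B cell genes had 0.25 (0.616), with Cd79b at 2.73 (SE 1.04), monocyte 1.34 (0.0691), CD8 T and NK cell 0.35 (0.852), and the 3 dendritic cell genes an adjusted p of 0.457. Neutrophil, erythroid, platelet, stromal and sex-linked genes had fewer than 3 members tested. By edgeR fold changes, the median, the mean and the test differed in sign for 4 of the lists that were not called. The edgeR medians of effector Treg (-0.0957), B cell (-0.245) and CD8 T and NK cell genes (-0.63) had the other sign to the voom medians given here. Xist, transcribed from the inactive X chromosome, stood at 23.1 and 23.6 CPM in SRC-3KO and 66.4 and 37.6 CPM in control.

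Control no-tumor replicate 1, named as wild type where the other controls are named as Foxp3-Cre, stood apart from the other 3 no-tumor libraries. Its Jchain level was 0.0397 CPM against 50.1 to 109 CPM, and its ribosomal protein genes held 1.64% of counts against 5.08% to 7.01%. Its median log2 ratio to the others was -1.68 for genes with a GC content under 40% and 2.27 at 55% or more. Without it, edgeR called 1 gene, the neutrophil gene S100a9 (adjusted p = 0.0404, chosen after its values were seen), and camera 4 lists. Treg identity genes then rose as a set (median 0.36, adjusted p = 0.00874, 4 over the list alone), cell cycle genes stayed lower (-0.45, adjusted p = 0.000465), ribosomal protein genes were lower in place of higher (-0.34, adjusted p = 1.03e-10), and neutrophil genes were lower (adjusted p = 0.00132). These calls use the preset correlation, and an estimated one was not used in this setting. With all libraries it gave 0.80 for Treg identity and cell cycle genes and 0.881 for ribosomal protein genes. Oxidative phosphorylation (-0.05, adjusted p = 0.979), the type I (0.46, 0.550) and gamma interferon lists (0.16, 0.0881), nuclear receptors (-0.70, 0.117) and conventional CD4 T cell genes (-0.87, 0.0826) lost their calls, the last also without control replicate 2 (0.178). Control replicate 2 held 51.9 CPM of S100a8 and 105 CPM of S100a9, and without it edgeR called 7434 genes.

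Combined over both states, 6 of 21 lists were called. Cell cycle genes had medians below 0 in both states (-1.09 without and -0.80 with a tumor, combined camera adjusted p = 3.62e-19). Treg identity medians were above 0 in both (0.61 and 0.63, adjusted p = 0.000143), and cytokine medians below 0 in both (-0.82 and -1.55, adjusted p = 0.0021). Without a tumor alone, Treg identity and cytokine genes were not called (camera adjusted p = 0.211 and 0.330). There, cytokine list medians relative to the control mean were 0.02 and -0.37 in SRC-3KO and 0.08 and -0.08 in control. Conventional CD4 T cell genes were also lower (-1.19 and -0.06, adjusted p = 0.0244). TGF-beta signalling (-0.29 and 0.70, adjusted p = 0.00853) and B cell genes (0.25 and -2.17, adjusted p = 0.000224) were called with medians that differed in sign between the states. By edgeR fold changes the B cell median without a tumor was -0.245, the same sign as with a tumor. No list passed with an estimated correlation (smallest adjusted p = 0.395) or by fry (0.0609). Of 11674 genes, 0 passed (smallest adjusted p = 0.232), with 595 at an unadjusted p under 0.05, and with limma-voom in place of edgeR also 0 (654). With DESeq2 for the no-tumor libraries 27 genes passed, 3 up and 24 down. Without control no-tumor replicate 1 the gene count was 158, and without control no-tumor replicate 2 it was 1182.

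**Figure D3:**
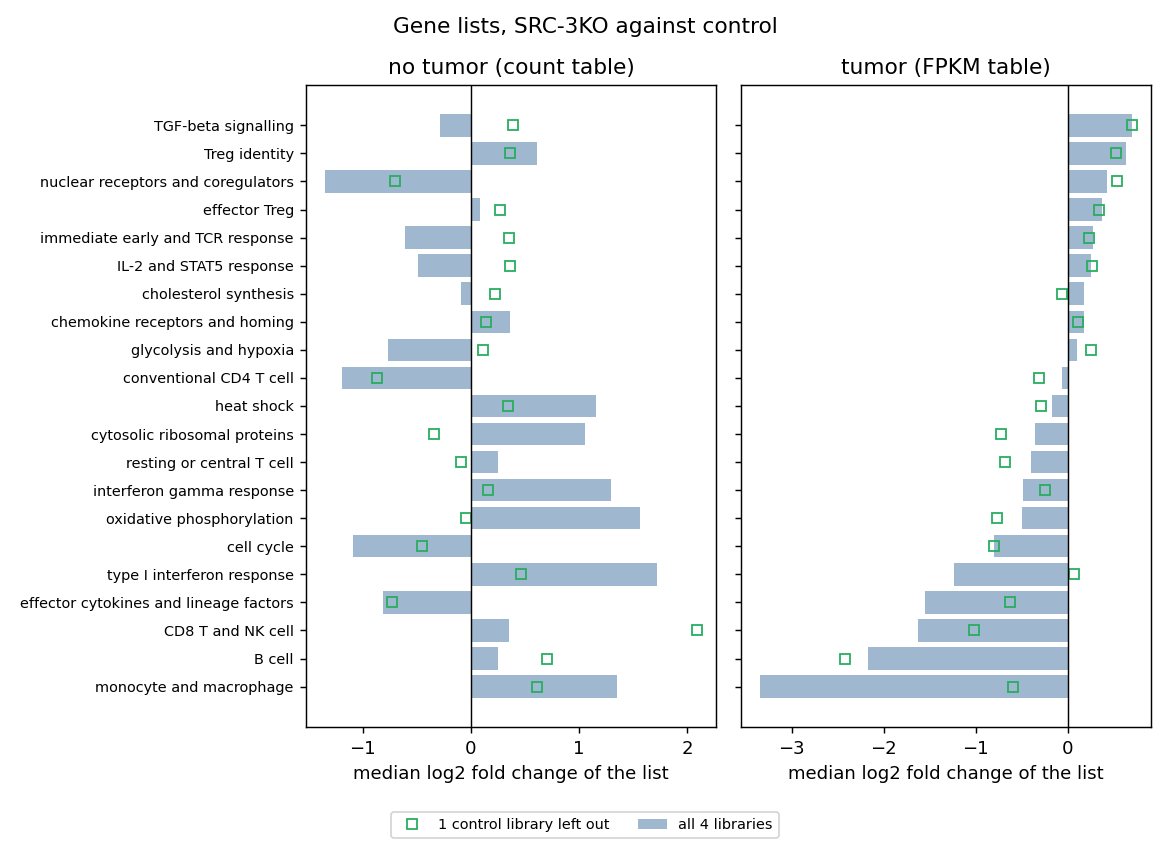
Median log2 fold change (SRC-3KO over control) of each gene list without a tumor and with one. Bars are all 4 libraries and squares leave out control replicate 1 (no tumor) or control replicate 2 (tumor); cell cycle was at -1.09 and -0.80, and moved to -0.45 and -0.80.

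The medians of type I interferon and of oxidative phosphorylation genes ran in opposite directions in the states (1.72 and 1.56 without a tumor, -1.24 and -0.50 with one), and neither list difference was tested. Without control no-tumor replicate 1 the no-tumor medians were 0.46 and -0.05, and without control tumor replicate 2 the type I median with a tumor was 0.07. Per gene, the difference between the genotype effects with and without a tumor passed in 0 of 11674 genes. The test was on the 2 limma estimates (smallest adjusted p = 0.571), with 469 at an unadjusted p under 0.05. What this test can detect at the dispersion of these counts was not simulated. Across genes, the 2 sets of fold changes had a Spearman rho of -0.33 and the same sign in 35.0% of genes, and rho was 0.04 without control no-tumor replicate 1 and control tumor replicate 2. Without control no-tumor replicate 2, 5718 genes passed. Tumor against no tumor was not tested in either genotype, because the libraries of each state are in tables of different units that were normalized separately.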

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

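The list medians below came from planned tests, but the comparison of their directions between states and the tests of explanations were chosen only after the result was seen.

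What singled out 5 lists was that camera called them in both states and that both SRC-3KO libraries of a state moved opposite to both of the other. The tumor median minus the no-tumor median was -2.96 for type I interferon response, -1.78 for interferon gamma response, 1.77 for nuclear receptors and coregulators, -2.06 for oxidative phosphorylation and -1.41 for cytosolic ribosomal proteins. These differences were not tested. With control no-tumor replicate 1 left out, the no-tumor medians of the ribosomal and oxidative phosphorylation lists were -0.34 and -0.05, the same sign as with a tumor, and those of the type I and gamma interferon lists were 0.46 and 0.16. With control tumor replicate 2 left out, the type I interferon median with a tumor was 0.07. With the GC and length trend removed, the nuclear receptor medians were 0.08 without and 0.06 with a tumor, but they stayed opposite without those 2 controls, at -0.70 and 0.54, and at -0.60 and 0.23 with the trend also removed.

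Control no-tumor replicate 1 stood apart from the other no-tumor libraries, with low levels of GC-poor and high levels of GC-rich transcripts. Genes of small and ribosomal RNAs held 4.15% of its counts, against 0.10% to 0.12% in the others. It had 23941 genes above 0, against 15333 to 17915. The cause of these 2 differences was not tested. A few genes taking most of the counts are argued against, since its 10 highest genes held 9.93% of counts. A trend with GC content and transcript length may be part of the cause, since its removal took away 44.1% of the variance of the library's log2 ratios. Whether the trend is the whole cause stays open: after its removal, the smallest SD of this library's ratios was 1.02 times the largest among the other 3. A first version of that measure gave 1.09, and no biological explanation was tested.

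Control tumor replicate 2 held transcripts of neutrophils and monocytes, with S100a8 at 1851, S100a9 at 1570 and Lyz2 at 1108 FPKM. A GC and length trend is argued against, since the median log2 ratio of the 2 lists to the other libraries was 5.52 after its removal. Whether neutrophils and monocytes were among the sorted cells stays open. Of the members, 27 of 30 lay above 2 times the highest other library, but this restates the pattern. The share of such cells after the sort for GFP was not measured. Control tumor replicate 1 had 3 of 13 neutrophil and 6 of 17 monocyte members at 1 FPKM or more. SRC-3KO tumor replicates 1 and 2 had 5 and 6 monocyte members at that level, and 0 neutrophil members each. No biological explanation was tested.

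Fold changes with a tumor rose with transcript length across genes (Spearman rho 0.42). A trend of control tumor replicate 1 alone is argued against, since rho was 0.266 without it. The ratio of control tumor replicate 1 to replicate 2 also moved with length (rho -0.30). Libraries of the same genotype thus differed by a length trend too. After removal of the trend the cell cycle median was -0.76 (quartiles -1.07 to -0.51) and the TGF-beta signalling median 0.41 (0.10 to 0.82). This argues against the trend as the whole cause of either, but less so for TGF-beta signalling. Without control tumor replicate 2, removal took the TGF-beta signalling median from 0.70 to 0.28. Removal was also not complete, and with all libraries a rho of 0.08 with length remained. For nuclear receptors and coregulators, with all libraries, the median went from 0.42 to 0.0565 (-0.07 to 0.45), so the trend may be the whole cause of that change. Whether the trend is technical or follows the loss of SRC-3, which the design names, stays open.

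In the combination of both states, 18 of the 18 splits of the libraries gave as many genes as the real one, which had 0, and the highest other split had 0. With 0 real calls every split must give as many, so this count cannot tell anything about the grouping. These splits are also too few for a share under 0.05.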

How the results depend on the processing

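The alternatives with GC and length removal, median-of-ratios or quantile scaling, Satterthwaite degrees of freedom and the joint omission of control no-tumor replicate 1 and control tumor replicate 2 were chosen after seeing the data. With a library left out, the lone sample is assumed to vary like the other group. Where a control is left out, the spread then comes from the SRC-3KO pair, which varied less than the controls.

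Single genes and lists changed sign in 10 of the alternative values. Where the direction of the test was kept, 935 values kept their side of the threshold, 288 no longer passed and 2 newly passed (Ncoa3 and Foxp3 without a tumor, without control replicate 2). A further 7 reversed in direction and are counted apart, and some of these no longer passed either. The ribosomal list without a tumor reversed to -0.34 without control replicate 1 (highest with 1 library left out, 2.39) and -0.31 with the trend also removed. With a tumor, type I interferon reversed to 0.0697 without control replicate 2 (lowest with 1 library left out, -1.86) and 0.12 with the trend also removed, where cholesterol synthesis was -0.0659 and Tgfbr2 -0.0386. Cholesterol synthesis was also -0.0613 without control replicate 2. Without a tumor, oxidative phosphorylation was -0.0482 without control replicate 1 and nuclear receptors 0.0760 with the trend removed. Ncoa3 with a tumor was 0.19 without SRC-3KO replicate 2 and -0.56 without SRC-3KO replicate 1. The number of genes called without a tumor went from 0 to 86 with DESeq2, 70 with no filter and 14 without control replicate 1 and with the trend removed, and ranged from 0 to 7434 with 1 library left out. With a tumor it went from 14 to 1 with no filter (Mir24-2), 30 with a filter at 5 FPKM, 7 with a pseudocount of 0.1, 6 without segment, haemoglobin and ribosomal protein genes, 6 with median-of-ratios, 34 at an adjusted p under 0.10, 106 without control replicate 2 and with the trend removed, and from 31 to 2510 with 1 library left out. A replicate block, which pairs libraries by their number, gave 72 genes, though the differences between replicates correlated by only 0.0357 across genes between the groups. Combined over states, the count was 27 with DESeq2, 35 with no filter, 1122 without those 2 controls, 1034 with the trend also removed, and 0 to 1182 with 1 library left out. The difference between states called 0 to 5718 genes with 1 library left out, and with Satterthwaite degrees of freedom 0 with all libraries, 7373 without control no-tumor replicate 2, 1263 without those 2 controls and 470 with the trend also removed. Lists called ranged from 5 to 13 in both states, 4 to 10 without and 10 to 16 with a tumor with 1 library left out. With that control of each state left out and the trend removed they were 4 and 8, and with an estimated correlation or fry 0 each. RLE factors shifted the median of all genes without a tumor by -0.13. The cause of these changes was not tested. Not run were alternatives that need counts of all 8 libraries and all of those for tumor against no tumor. Without counts, what depth limits in the tumor libraries is unknown.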

Other observations

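The tests below were chosen after the result was seen: control no-tumor replicate 1 and control tumor replicate 2 were left out together, which leaves 1 control library in each state, assumed to vary like the SRC-3KO pair. The control pairs varied more. Without a tumor, log2 ratios across genes had an SD of 2.64 between the controls and 1.17 between the SRC-3KO libraries. With a tumor, the controls correlated by 0.937 and the SRC-3KO libraries by 0.979. Too many genes may therefore pass below, with p-values that are too small.

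With these libraries left out, 1122 genes passed in both states combined, 608 of them up, and with the GC and length trend also removed 1034 passed, 357 of them up. The genes here were chosen after their values were seen. Lower were the cytokine Csf2, by -2.89 without and -2.35 with a tumor, the chemokine Ccl3 by -1.01 and -2.99, and the membrane protein Ifitm3, by -2.03 and -3.18. Aurkb (-2.92 and -1.88) and Ighm (-1.19 and -1.56) were lower too. Higher were the costimulatory receptor Tnfrsf9 (1.01 and 0.97), Itgb8 (1.16 and 1.71), Smad7 (1.83 and 1.65) and the stress gene Gadd45g (1.48 and 0.90). All of these genes passed with the GC and length trend removed as well. Without a tumor, 3 of them were not apart from the omitted control. Gadd45g stood at 272 and 285 CPM in SRC-3KO, 277 CPM in the omitted control and 92.8 CPM in the kept one. Smad7 and Ighm in SRC-3KO lay between the omitted control (37.2 and 74.9 CPM) and the kept one (3.24 and 309 CPM). Csf2, Ccl3, Ifitm3 and Aurkb lay below both no-tumor controls, and Tnfrsf9 and Itgb8 above both.

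As sets under camera's preset correlation, TGF-beta signalling (medians 0.39 without and 0.70 with a tumor, adjusted p = 5.86e-06) and Treg identity genes (0.36 and 0.53, adjusted p = 1.89e-05) had medians above 0 in both states, and cell cycle (-0.45 and -0.80, adjusted p = 1.82e-10) and ribosomal protein genes (-0.34 and -0.72, adjusted p = 2.21e-29) medians below 0 in both. These 4 were also called with the GC and length trend removed, with TGF-beta signalling medians of 0.26 and 0.28. Immediate early genes (0.35 and 0.23) were too, with medians of 0.29 and 0.04. With all libraries, the no-tumor medians of TGF-beta signalling, immediate early and ribosomal protein genes had the other sign, at -0.29, -0.61 and 1.06. Those of Treg identity and cell cycle genes kept theirs, at 0.61 and -1.09. The ribosomal median with a tumor depended on which control was left out. It was -0.00358 without control tumor replicate 1 in place of replicate 2. Without a tumor alone, TGF-beta signalling was not called, so its call rests mainly on the tumor libraries. Immediate early genes were not called there either, but their median was larger without a tumor than with one. With the trend removed they were called in neither state alone. IL-2 and STAT5 response (adjusted p = 0.0125) and cytokine genes (0.0312) were called, but not with the trend removed (0.142 and 0.0863). Oxidative phosphorylation was called lower over both states (adjusted p = 1.02e-09), but its median without a tumor was -0.05 (adjusted p = 0.979), so the call rests on the tumor libraries. B cell genes were called lower with medians of 0.70 and -2.42 (adjusted p = 0.0119). An estimated correlation was not used in this setting, and with all libraries it left 0 lists called over both states (smallest adjusted p = 0.395). No explanation was tested.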
